A study of Gallus gallus with 24 samples.

How the data were processed

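Total RNA from chicken embryo ventricles was hybridised to Affymetrix chicken arrays with 2 arrays for each of 12 pools. Per the labels' protocols, the outflow tract was banded or the left atrial appendage partly tied in the egg on day 4, and tissue of 6 to 12 specimens was pooled for each condition. The RNA was purified on RNeasy columns, assessed on a Bioanalyzer, and turned into biotin-labelled cRNA with a SuperScript cDNA kit and an Enzo transcription kit, per the same protocols. The 2 arrays of a pool are technical replicates of 1 RNA, per the labels, so the pool was the unit of every test.

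The deposited values were taken as log2 signal, a unit that their range of values fits. Per the submitters' processing notes, GCRMA and MAS5 were used, with no versions and no roles given. How the values were centred or scaled between arrays is not given in the sources used here. Over all probe sets the array medians ran from 4.02 to 4.14, and over the tested probe sets from 8.93 to 9.07. The only table used was the series' table of values, and raw scans were not used here.

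Of 38535 probe sets, 153 are controls or reporters and 689 carry names outside the chicken gene design. Both kinds were left out of the tests. A probe set was tested where its pool mean reached 5 on the log2 scale in at least 1 of the 12 pools. This left 18930, of which 15542 have 1 gene symbol in the array annotation supplied, 79 have several and 3309 have none. No gene was named from a probe set with several symbols. Symbols are those of the annotation and can be old. A gene is represented by its probe set with the highest mean over all arrays, for 9202 genes. The 59 control probe sets without spiked RNA lay between 1.61 and 3.35. Where a compared pool lay under the filter level of 5, the fold is given as a lower bound ("at least"), with every pool value under 5 set to it. Slopes, errors, p-values and list medians use the values as deposited, unless a median is given at its bound.

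The 2 arrays of each pool were averaged, and the pool means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings). Benjamini-Hochberg adjusted p under 0.05 was the threshold, and errors beside log2 values are standard errors from these fits. Change with age was a slope on day with a chamber term (left, both, right) in the 9 normal pools, with 6 residual degrees of freedom. The E6 minus E4, E10 minus E6 and left minus right differences came from a fit with stage as a factor and the same chamber term, with 3 residual degrees of freedom. The operated pools were compared with normal pools of their own stage and chamber in a fit of all 12 pools with 2 residual degrees of freedom. There each compared pool has its own mean, so the difference is a plain difference of pools, and a lone pool is assumed to vary like the E6 and E10 pools. The p-values therefore measure scatter of pools around the fitted terms, with no repeat of a condition. It holds pooling, dissection and labelling, and also real departures from those terms, such as change with age off a straight line. In the fit of all 12 pools it comes from 2 contrasts. They are the chamber difference at E6 against E10, and the E6 pool of both ventricles against the mean of left and right E6. Chamber differences that change with stage, or tissue particular to an E6 pool, thus widen the errors there.

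The 34 gene lists were written from general knowledge of heart and embryo tissues. They were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Lists with under 5 tested genes were not tested. List medians were also set against 10000 random lists matched on mean expression. Counts of list members past the test use adjustment over all probe sets, or over the list alone where so stated.

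Named genes follow a rule. For each comparison they are up to 12 genes with the highest and up to 12 with the lowest difference among those past the threshold whose arrays do not overlap between the compared pools (slope and left minus right: the same sign in each chamber or stage). Where fewer than 6 pass in a direction, the largest differences that meet the other condition fill up to 6. Up to 4 members with the largest difference are added per list past its test and per cell type list, with 12 cardiac genes in every comparison. The design, the gene lists, the rule for named genes and the alternatives listed here, apart from those named as added, were chosen before the data were examined.

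The fits were tested on simulated data, with 200 of 18930 probe sets changed. For a slope of 1 per day 99% were recovered, but only 18 of the real slopes were that large, and smaller slopes were not simulated. For a change of 1 on the log2 scale 44% were recovered for left minus right. At that size 0% were recovered for E6 minus E4, E10 minus E6, CTB and every ligation result. For a change of 2 on the log2 scale the share was 64.5% for E6 minus E4, 80.5% for E10 minus E6, 83% for left minus right, 61.5% for the mean of the ligated ventricles, and 0% for CTB, each ligated ventricle and the left minus right ligation difference. For a change of 4 these last shares were 69%, 82% and 83% for left and right, and 52.5%. In the list test for CTB 1 of 30 simulated lists of 20 genes was shifted by 1 and was recovered, and 0 of the unchanged lists were called. The simulated genes varied independently, so this cannot show how often lists whose genes vary together are falsely called. The shift of 1 is also larger than every list median called for CTB.

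The alternatives were a single array per pool, arrays counted as samples with and without the replicate number as a block, quantile normalization, median centring, no filter, a filter at 7, a trended and robust variance, an additive model for the operated pools, each normal pool left out in turn, the 6 single-ventricle pools alone, and for lists an estimated correlation and the mean of all probe sets of a gene. Leaving out the left and right E6 pools and removing the part of the ligated pools parallel to those pools were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Probe set sequences and chromosome positions were not used here.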

Results

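Gene expression in the embryonic chicken heart was measured on 24 arrays of 38535 probe sets each. The arrays hold 12 pools of ventricular RNA, each from 6 to 12 specimens and each run on 2 arrays. The 9 normal pools cover both ventricles together on embryonic day 4, 5 and 6 (E4, E5, E6), and the left and the right ventricle apart on E6, E8 and E10. The other 3 pools come from hearts operated on in the egg on day 4. They are both ventricles at E5 after conotruncal banding (CTB), and the left and the right ventricle at E8 after a partial tie was placed on the appendage of the left atrium (LAL).

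No condition has a replicate pool, so n = 1 pool for every condition, and the number of pools sets how finely changes can be told from chance. Arrays of the same pool lay close together, with a median SD of 0.05 on the log2 scale. Normal pools scattered around the fitted day and chamber terms with a median SD of 0.17. The tests below cover 18930 probe sets, 15542 of them with a single gene symbol for 9202 genes, and every adjusted p is from limma.

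Which transcripts rose or fell with age in the normal ventricle? Across the 9 normal pools, FGF1, a fibroblast growth factor, rose by 1.40 ± 0.20 (adjusted p = 0.00307) log2 units per day. FABP5 and CD36, which bind and take up fatty acids, rose by 1.17 ± 0.11 (adjusted p = 0.000906) and 0.89 ± 0.12 (adjusted p = 0.00247), and COL14A1, a collagen that binds to other collagen fibrils, by 0.89 ± 0.11 (adjusted p = 0.00228). AQP3, a channel for water and glycerol, fell by 1.19 ± 0.16 (adjusted p = 0.00289) per day, CBLN1, a secreted cerebellin, by 1.13 ± 0.14 (adjusted p = 0.00215), and LHX9, a LIM homeobox transcription factor, by 1.10 ± 0.08 (adjusted p = 0.000424). MYBPC1, the slow skeletal form of myosin-binding protein C, fell by 0.94 ± 0.11 (adjusted p = 0.00196). In total 1677 probe sets rose and 2259 fell. Counted by the probe set that represents each gene, 784 genes rose and 1322 fell. More probe sets rose than fell with median centring (1967 and 1790) and without right E10 (809 and 768). Over the probe sets of a gene the slope ran from -1.10 to -0.42 for LHX9. FGF1, AQP3, CBLN1, LHX9 and MYBPC1 were under 5 in some of these pools, so the size of their slopes is inexact.

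Lists of fatty acid metabolism and oxidative phosphorylation leaned upward with age, while the hypoxia and glycolysis list was not called (list adjusted p = 0.153). Of 24 measured genes of fatty acid metabolism, 11 rose, 0 fell and 13 did not pass (list adjusted p = 1.20e-09, adjusted p = 0.393 with an estimated correlation). Adjusted over the list alone, 16 rose. Besides CD36, they include LPL, lipoprotein lipase, at 0.23 ± 0.04 (adjusted p = 0.00400) per day, and PPARGC1A, a coactivator of mitochondrial biogenesis, at 0.19 ± 0.03 (adjusted p = 0.00649). In oxidative phosphorylation 3 of 38 measured genes rose and 0 fell, and the slopes of all 38 were positive (median 0.04 per day, list adjusted p = 4.47e-07, adjusted p = 0.509 with an estimated correlation). The calls of LPL and PPARGC1A ended in the 6 single-ventricle pools alone. Over all alternatives their adjusted p ran from 1.03e-13 to 0.0555 and from 2.33e-13 to 0.112, highest in those 6 pools. The low end of this and each later range of adjusted p comes from arrays counted as samples. There hybridisation noise stands in place of the scatter between pools.

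Lists of matrix, endothelial and contractile genes also leaned upward, with a minority of members past the test. Of 38 measured genes of extracellular matrix and fibroblasts, 12 rose, among them COL14A1 and BGN, the proteoglycan biglycan, 5 fell and the rest did not pass (list adjusted p = 2.37e-05, adjusted p = 0.591 with an estimated correlation). Among 23 endothelial genes 6 rose and 2 fell (list adjusted p = 0.00343, adjusted p = 0.509 with an estimated correlation), with VWF, von Willebrand factor, at 0.41 ± 0.05 (adjusted p = 0.00185) per day. Of 34 genes of the contractile apparatus 10 rose, such as PDLIM5, a protein of the Z-disc, at 0.26 ± 0.03 (adjusted p = 0.00122) (0.07 to 0.47 over its 5 probe sets), and 2 fell (list adjusted p = 1.14e-05, adjusted p = 0.509 with an estimated correlation). MYL4, the essential myosin light chain of atrial and embryonic muscle, fell by 0.37 ± 0.03 (adjusted p = 0.000424) per day. MYLK, the kinase that phosphorylates smooth muscle myosin, rose by 0.28 ± 0.02 (adjusted p = 0.000664), with slopes of up to 0.63 on its other probe sets.

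The calcium handling list (18 measured, 3 rose, 2 fell, list adjusted p = 0.00703, adjusted p = 0.509 with an estimated correlation) and the immediate early list (7 measured, 1 rose, 0 fell, list adjusted p = 0.0233, adjusted p = 0.591 with an estimated correlation) had positive medians. So had the load and stress list (18 measured, 4 rose, 1 fell, list adjusted p = 0.0290, adjusted p = 0.509 with an estimated correlation), whose call ended under quantile normalization (adjusted p = 0.0645, against 0.0446 with median centring). Ventricular muscle markers had slopes near 0. The slope of NPPA, the natriuretic peptide A gene, was 0.07 ± 0.02 per day (adjusted p = 0.0704), that of MYH15, the ventricular myosin heavy chain of the chick, 0.02 ± 0.02 (adjusted p = 0.356) and that of TNNT2, cardiac troponin T, 0.01 ± 0.02 (adjusted p = 0.663).

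Genes of the endocardial cushions and valves, mesenchyme formed at the inlets and the outlet of the ventricles, fell with age: 9 of 15 measured members fell and 0 rose (median -0.27 per day, list adjusted p = 0.0125, adjusted p = 0.509 with an estimated correlation). COL9A1, a cartilage-type collagen under 5 in some pools, fell by 0.55 ± 0.07 (adjusted p = 0.00228) and PRRX1, a homeobox gene of mesenchyme, by 0.44 ± 0.08 (adjusted p = 0.00691). NRG1, the growth factor with which the endocardium signals to the myocardium, fell by 0.39 ± 0.04 (adjusted p = 0.00112) on its brighter probe set, while its other probe set had a slope of 0.03. The neurofilament genes NEFM and NEFL fell by 0.88 ± 0.07 (adjusted p = 0.000542) and 0.61 ± 0.04 (adjusted p = 0.000424), with the other NEFM probe set at -0.48. HBZ, an embryonic globin, fell by 0.64 ± 0.10 (adjusted p = 0.00517).

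Leaving out 1 pool moved the count of 3936 most for right E10, to 1577 (1533 shared), and for E4, to 2224 (2086 shared). In the 6 single-ventricle pools alone the count was 1349, and the calls of COL9A1 and PRRX1 ended (adjusted p over all alternatives 1.27e-10 to 0.0526 and 1.05e-09 to 0.0979, highest in those pools).

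**Figure D1:**
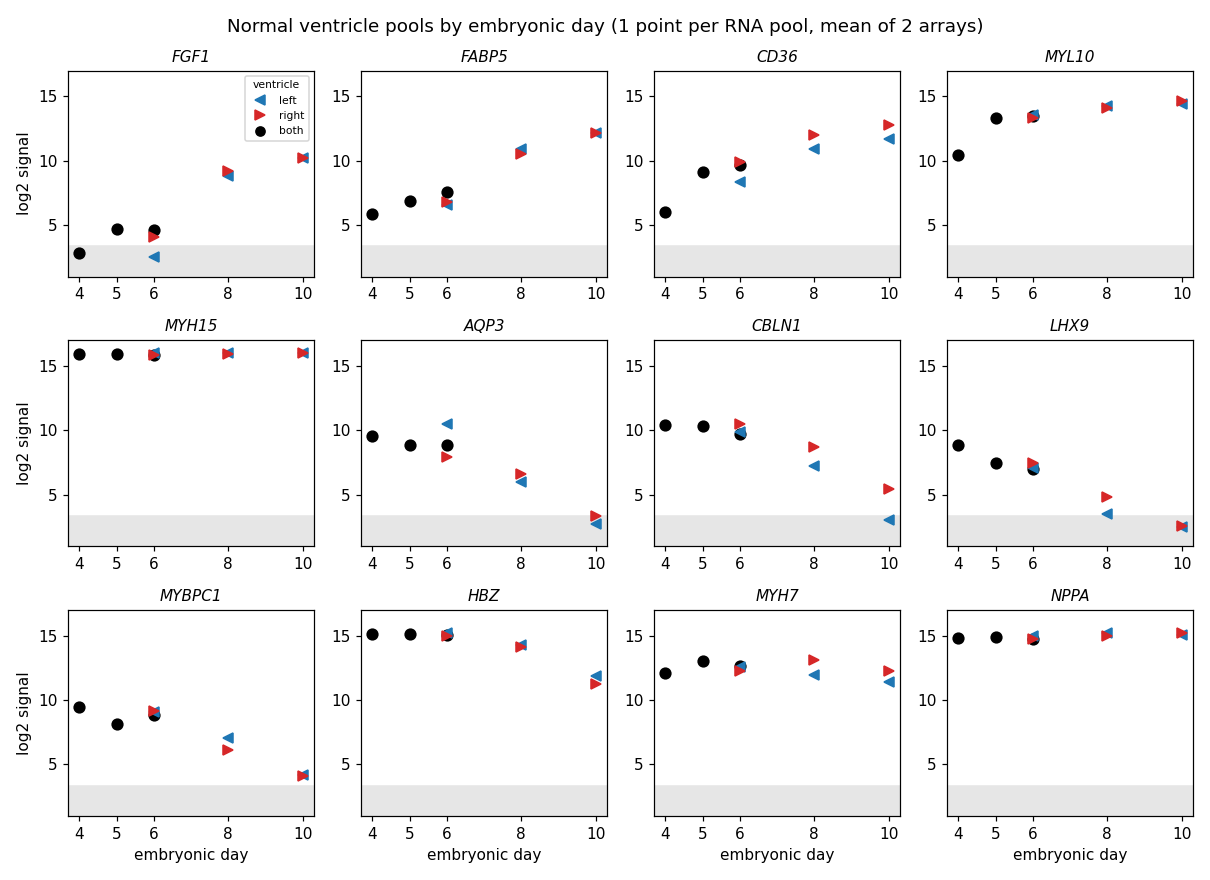
Log2 signal of 12 genes (vertical axis) against embryonic day (horizontal axis) in the 9 normal pools, 1 point per pool, with triangles for left or right and circles for both ventricles. Log2 FGF1 went from 2.80 at E4 to 10.22 in left E10, and the grey band ends at 3.35, the highest unspiked control.

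What changed early, between E4 and E6? AGR2, a protein of mucus-secreting epithelia, had a log2 level of 9.53 at E4 and 1.92 at E5, and fell at least 23.1-fold to E6 (adjusted p = 0.00360, 1 E4 and 3 E6 pools). With E4 a single pool, limma takes its spread from the E6, E8 and E10 pools. A change from E4 can also not be told from a trait of that pool. TFF3, a trefoil peptide of mucosal surfaces, fell at least 4.47-fold (adjusted p = 0.00102) and LGALS3, the galectin-3 gene, at least 5.60-fold (adjusted p = 0.00360). TSPAN2, a tetraspanin, rose at least 3.11-fold (adjusted p = 0.00360). MYL10, a myosin regulatory light chain, rose by 2.98 ± 0.17 on the log2 scale, or 7.92-fold (adjusted p = 0.0105), and CD36 by 3.32 ± 0.29, or 9.97-fold (adjusted p = 0.0321).

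The matrix list had the smallest list adjusted p. Of 38 measured genes of extracellular matrix and fibroblasts none passed over all probe sets, 12 rose when adjusted over the list alone, and 36 had positive differences (median 0.47, list adjusted p = 6.32e-13, adjusted p = 0.495 with an estimated correlation). OGN, osteoglycin, was at least 11.7-fold higher at E6 (adjusted p = 0.0666) and COL14A1 2.83 ± 0.32 higher on the log2 scale (adjusted p = 0.0541). Fatty acid metabolism moved up, with 1 of 24 past the test over all probe sets and 3 over the list alone (median 0.25, list adjusted p = 1.55e-07, adjusted p = 0.622 with an estimated correlation).

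Cell cycle genes moved down as a group, with 39 of 43 differences negative (median -0.26, list adjusted p = 5.10e-05, adjusted p = 0.622 with an estimated correlation). None passed over all probe sets and 1 over the list alone. CCNE1, the cyclin of entry into DNA synthesis, was -0.84 ± 0.13 on the log2 scale (adjusted p = 0.0979). Calcium handling genes moved up (median 0.34, list adjusted p = 0.000527, adjusted p = 0.622 with an estimated correlation), with SLN, the calcium pump regulator sarcolipin, at 1.58 ± 0.17 (adjusted p = 0.0533). So did the contractile list (median 0.12, list adjusted p = 0.00790, adjusted p = 0.781 with an estimated correlation) and the erythrocyte list (median 0.19, list adjusted p = 0.00790, adjusted p = 0.670 with an estimated correlation), in which 1 of 16 genes passed, HEMGN at 1.98 ± 0.15 (adjusted p = 0.0228). The 6 interferon response genes moved up by a median of 0.53 (list adjusted p = 0.00790, adjusted p = 0.622 with an estimated correlation), which was 0.00 with pool values under 5 set to 5.

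Liver transcripts stood apart in these pools. The mean log2 level of 9 liver genes was 9.24 in the E6 pool of both ventricles, against 5.39 in left E6, 4.73 in right E6 and 5.14 at E4. Of all probe sets, 39 rose and 27 fell between E4 and E6, and which direction held more turned with the setting. Those higher were 64 of 207 with no filter, 10 of 29 without left E6, 5 of 16 without right E6, 2 of 12 without either E8 pool and 5 of 15 without either E10 pool.

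The early count of 66 rests on few pools. Without left or right E8 it was 12 in each case, without left or right E10 15, without right E6 16, without left E6 29 and without the E6 pool of both ventricles 37. It was 111 with median centring, 207 with no filter and 100 with a trended and robust variance. With E6 taken from the pool of both ventricles alone it was 78, of which 26 were shared. The calls of AGR2, TFF3, LGALS3 and TSPAN2 held with each of these pools left out. That of MYL10 ended without right E6 (adjusted p = 0.0663) or either E8 pool (0.0840). For CD36 the adjusted p was 0.118 without right E6, 0.157 without either E8 pool and 0.114 without either E10 pool. Over all alternatives the adjusted p of MYL10 ran from 7.89e-17 to 0.0840 and that of CD36 from 3.55e-17 to 0.157. The HEMGN call ended without any 1 of the E6, E8 or E10 pools, its adjusted p running from 3.17e-08 to 0.126, highest without an E8 pool.

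What changed late, between E6 and E10? FGF1 rose at least 37.1-fold (adjusted p = 0.00946, 2 E10 and 3 E6 pools) and FABP5 by 5.17 ± 0.32 on the log2 scale, or 36.1-fold (adjusted p = 0.00588). MGP, matrix Gla protein, an inhibitor of calcification, rose at least 12.7-fold (adjusted p = 0.00956), and MB, the oxygen store myoglobin, 10.6-fold (adjusted p = 0.00808). CBLN1 fell at least 28.0-fold (adjusted p = 0.00808) and MYBPC1 at least 16-fold (adjusted p = 0.00472). HBZ fell by 3.51 ± 0.15, or 11.4-fold (adjusted p = 0.00463), with the beta-type embryonic globin gene HBE down by 1.91 ± 0.15 (adjusted p = 0.00825).

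All 38 genes of oxidative phosphorylation had positive differences, none past the test alone (median 0.19, list adjusted p = 1.72e-07, adjusted p = 0.573 with an estimated correlation). Of 24 fatty acid genes 2 rose, CD36 by 2.92 ± 0.23 (adjusted p = 0.00870), and 8 over the list alone (list adjusted p = 2.50e-07, adjusted p = 0.573 with an estimated correlation). Of 38 matrix genes 10 rose and 3 fell (list adjusted p = 0.00263, adjusted p = 0.573 with an estimated correlation), and of 23 endothelial genes 3 rose, VWF by 1.94 ± 0.21 (adjusted p = 0.0148), and 1 fell (list adjusted p = 0.00336, adjusted p = 0.573 with an estimated correlation). The contractile list moved up (3 rose, 2 fell, list adjusted p = 0.000187, adjusted p = 0.573 with an estimated correlation) while its member MYL4 fell by 1.62 ± 0.13 (adjusted p = 0.00826). Load and stress genes (18 measured, 1 rose, 1 fell, list adjusted p = 0.00632, adjusted p = 0.573 with an estimated correlation) and immediate early genes (7 measured, 1 rose, 0 fell, list adjusted p = 0.0106, adjusted p = 0.593 with an estimated correlation) moved up.

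In this interval 499 probe sets rose and 619 fell. More rose than fell with quantile normalization (635 and 584), with median centring (668 and 643) and without the E6 pool of both ventricles (447 and 404). The liver transcripts of the E6 pool of both ventricles lie on its E6 side. Without right E10 the count of 1118 became 30, without left E10 160, without right E6 299, without left E6 450, without either E8 pool 340 and with no filter 529. With the left and right E6 pools both left out it was 252, of which 185 were shared. MGP, CBLN1 and HBZ kept their calls in every leave-out. Without right E10 the calls of FGF1 (adjusted p = 0.0811), FABP5 (0.0671), MB (0.0831), MYBPC1 (0.0509), HBE (0.0671), CD36 (0.0831), VWF (0.116) and MYL4 (0.0671) ended. Without left E10 so did those of FGF1 (0.0660), MB (0.0592), CD36 (0.0654), VWF (0.0911) and MYL4 (0.0589). The VWF call also ended without right E6 (0.0577), and that of HBE without the left and right E6 pools. Over all alternatives the adjusted p ran from 5.04e-15 to 0.0811 for FGF1, 1.04e-15 to 0.0671 for FABP5, 1.21e-17 to 0.0831 for MB and 1.89e-13 to 0.0509 for MYBPC1. It ran from 9.06e-15 to 0.0678 for HBE, 1.95e-17 to 0.0831 for CD36, 2.48e-14 to 0.116 for VWF and 5.71e-15 to 0.0671 for MYL4.

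Do the left and the right ventricle of normal hearts differ? No probe set passed in limma, with 2155 at unadjusted p under 0.05 and a smallest adjusted p of 0.0904. The values that follow had the same sign at E6, E8 and E10. SLN was 1.89 ± 0.12 higher in the left on the log2 scale, or 3.70-fold (adjusted p = 0.0904), and HTR2A, a serotonin receptor gene under 5 in most of these pools, had the same adjusted p. ZPLD1 was at least 7.87-fold higher in the right (adjusted p = 0.110; its other probe set was at -1.70) and ADCY8, an adenylyl cyclase, at least 6.32-fold higher (adjusted p = 0.113). In the left against the right, the BMP growth factor genes BMP5 and BMP2 were -2.70 ± 0.51 (adjusted p = 0.188) and -1.84 ± 0.33 (adjusted p = 0.177), and NR2F2, an orphan nuclear receptor of atrial muscle and veins, was at least 4.06-fold higher in the right (adjusted p = 0.283).

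Several lists stood higher in the right ventricle. Adjusted over each list alone, 7 of 15 cushion and valve genes were lower in the left and 1 higher (median -0.70, list adjusted p = 0.000507, adjusted p = 0.364 with an estimated correlation). For matrix and fibroblast genes it was 6 lower and 1 higher of 38 (median -0.26, list adjusted p = 1.23e-05, adjusted p = 0.364 with an estimated correlation), for leukocytes and thrombocytes 7 lower of 13 (median -0.65, list adjusted p = 0.000507, adjusted p = 0.585 with an estimated correlation). For the BMP and TGF-beta pathway it was 7 of 32 (median -0.13, list adjusted p = 0.00131, adjusted p = 0.364 with an estimated correlation) and for the endocardium 6 of 11 (median -0.39, list adjusted p = 0.00140, adjusted p = 0.364 with an estimated correlation). Smooth muscle and pericyte genes had a median of -0.24 (list adjusted p = 0.0346, adjusted p = 0.440 with an estimated correlation).

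Blood and skeletal muscle genes leaned to the left: the erythrocyte list had a median of 0.24 (list adjusted p = 0.0207, adjusted p = 0.585 with an estimated correlation) and the skeletal muscle list, with MYL1 at 0.59 ± 0.09 (adjusted p = 0.145), of 0.20 (list adjusted p = 0.0269, adjusted p = 0.440 with an estimated correlation). The cell cycle list also leaned left (median 0.07, list adjusted p = 0.0252, adjusted p = 0.618 with an estimated correlation), and its call ended under quantile normalization (adjusted p = 0.0590, against 0.0351 with median centring). TBX5, a T-box factor of the left ventricle, was at least 2.52-fold higher in the left (adjusted p = 0.370). By stage its left minus right value was -0.08 at E6, 2.32 at E8 and 2.20 at E10, the last against a right level under 5. With a trended and robust variance 5 probe sets passed, those of CADM2, TENM2, EPHA7, SLN and CSRP2, of which CADM2, TENM2, EPHA7 and CSRP2 were picked out after their values were seen. Across all probe sets the left minus right values correlated with r = 0.594 between E8 and E10, 0.342 between E6 and E8 and 0.125 between E6 and E10.

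**Figure D2:**
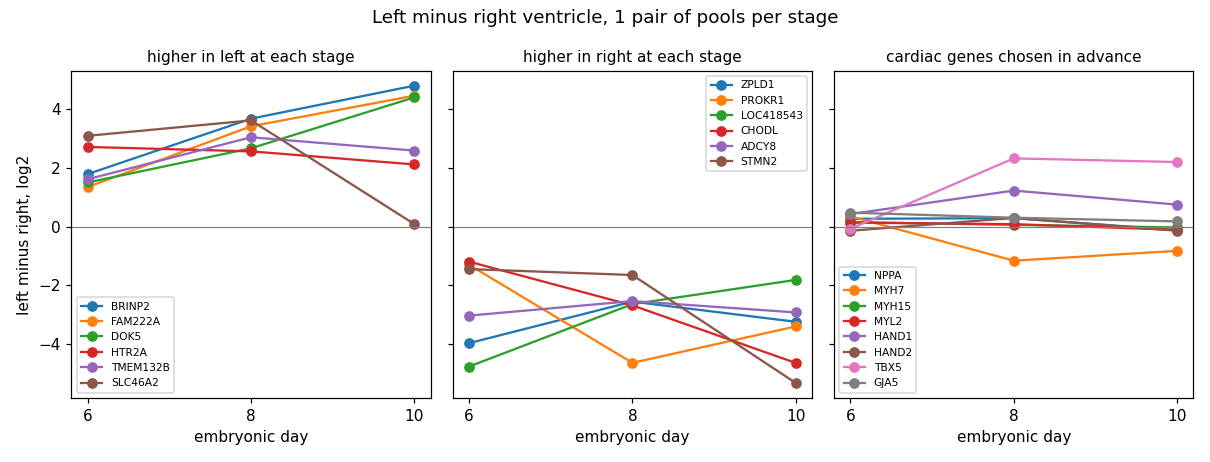
Left minus right ventricle difference on the log2 scale (vertical axis) against embryonic day (horizontal axis) in normal hearts, 1 pair of pools per stage and 1 line per gene. BRINP2 lies at 1.79, 3.67 and 4.80 on the left side and ZPLD1 at -3.97, -2.55 and -3.24 on the right as deposited, also where a level is under 5, and no gene shown passed the limma test.

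Does banding of the outflow tract change the ventricles within 1 day? CTB and normal hearts at E5 are 1 pool each, and limma takes its spread from the E6 and E10 pools. No probe set passed, with 132 at unadjusted p under 0.05. AVD, the gene for the biotin-binding protein avidin, came closest: it was under the highest unspiked control in every normal pool and at least 8.04-fold higher after banding, at log2 8.01 against 2.27 (adjusted p = 0.0772). CRABP1, which binds retinoic acid in the cell, was at least 2.20-fold higher (adjusted p = 0.809), and the mesenchymal homeobox gene PRRX2 at least 1.41-fold (adjusted p = 0.809). AVD passed with a filter at 7 (adjusted p = 0.0422) and with the additive model (0.00265), and with no other alternative that kept the pool as the unit.

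Among tissue lists, the cushion and valve list had the smallest adjusted p after banding, with 11 of 15 higher and 1 past the test over the list alone (median 0.24, list adjusted p = 0.000149, adjusted p = 0.477 with an estimated correlation). MSX2 and MSX1, homeobox genes of cushion mesenchyme, were 1.54 ± 0.70 and 0.99 ± 0.49. The retinoic acid and insulin-like growth factor list, which holds CRABP1, was higher too (median 0.15, list adjusted p = 0.000180, adjusted p = 0.477 with an estimated correlation), as were leukocyte and thrombocyte genes (median 0.11, list adjusted p = 0.0151, adjusted p = 0.932 with an estimated correlation). The liver list had a larger median of 0.45, which was 0.00 with pool values under 5 set to 5, and was not called (list adjusted p = 0.133). Ribosomal proteins were lower for 42 of 48 (median -0.06, list adjusted p = 0.00718, adjusted p = 0.932 with an estimated correlation) and erythrocyte genes for 15 of 16 (median -0.10, list adjusted p = 0.0354, adjusted p = 0.932 with an estimated correlation). Quantile normalization ended both of these calls (adjusted p = 0.632 and 0.189, against 0.0205 and 0.0332 with median centring), and the mean of all probe sets of a gene ended the ribosomal one (0.104).

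All 6 tested genes of the female W chromosome were higher after banding, 3 of them past the test over the list alone (median 0.91, list adjusted p = 1.46e-11, adjusted p = 0.477 with an estimated correlation). UBE2R2L, a W-linked gene, was 1.04 ± 0.30. In the same comparison 24 genes of the Z chromosome, of which males carry more copies, had a median of -0.09, and 15 of them were lower.

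How does ligation of the left atrial appendage alter the left ventricle by E8? No probe set passed in limma, with 768 at unadjusted p under 0.05 and 1 pool on each side. MSX2 of the cushion mesenchyme was at least 2.90-fold higher, though the cushion and valve list was not called in this comparison. PRRX1, also of the cushions, was 2.98 ± 0.45 on the log2 scale, ELN, the gene for elastin, 1.72 ± 0.45 and FBLN5, which helps to lay down elastic fibres, 1.77 ± 0.53. HAND1, a transcription factor of the left ventricle, was at least 5.40-fold lower. SPI1, a factor of the myeloid lineage, was at least 1.71-fold higher, and none of these genes came under an adjusted p of 0.195.

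Leukocyte and thrombocyte genes were higher in the ligated left ventricle, 13 of 13 (median 0.73, or 0.24 with pool values under 5 set to 5, list adjusted p = 0.000198, adjusted p = 0.600 with an estimated correlation). Matrix genes (median 0.22, list adjusted p = 0.0168, adjusted p = 0.600 with an estimated correlation), endocardial genes (median 0.25, list adjusted p = 0.0168, adjusted p = 0.600 with an estimated correlation) and apoptosis genes (median 0.18, list adjusted p = 0.0168, adjusted p = 0.600 with an estimated correlation) were higher as well. Oxidative phosphorylation was lower for 36 of 38 genes (median -0.11, list adjusted p = 0.00307, adjusted p = 0.600 with an estimated correlation). The contractile apparatus was lower for 27 of 34 (median -0.12, list adjusted p = 0.00912, adjusted p = 0.600 with an estimated correlation), with LMOD2, which lengthens actin filaments, at -1.16 ± 0.38. Cardiac transcription factors had a median of -0.20 (list adjusted p = 0.0477, adjusted p = 0.600 with an estimated correlation). Quantile normalization ended the calls of the contractile list (adjusted p = 0.0610) and of the transcription factors (0.0692), against 0.0118 and 0.0474 with median centring. The endocardial call ended with the mean of all probe sets of a gene (0.0581).

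Markers from outside the ventricle moved with these groups. All 9 tested liver genes were higher in the ligated left ventricle (median 3.0, or 1.62 with pool values under 5 set to 5, list adjusted p = 0.00574, adjusted p = 0.600 with an estimated correlation), ALB, serum albumin, at least 87.2-fold. The W chromosome list had a median of 0.64 (list adjusted p = 0.0168, adjusted p = 0.600 with an estimated correlation), beside a Z-linked median of -0.09.

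**Figure D3:**
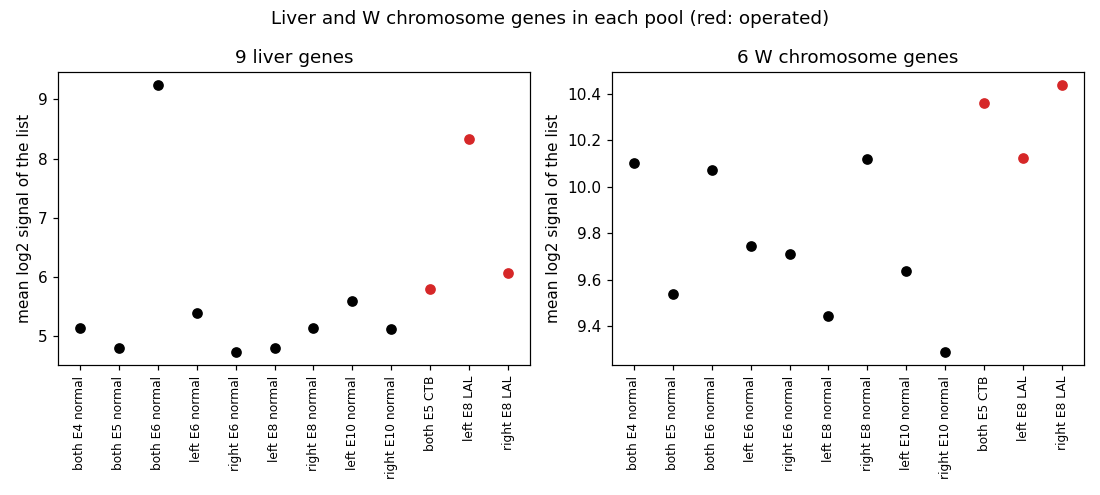
Mean log2 signal (vertical axes) of 9 liver genes and of 6 W chromosome genes in each of the 12 pools, 1 point per pool, operated pools in red. The liver mean is 9.24 in the normal E6 pool of both ventricles and 8.32 in the ligated left ventricle.

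And in the right ventricle after ligation? No probe set passed in limma, with 600 at unadjusted p under 0.05. AVD was at least 5.36-fold higher (adjusted p = 0.122). IL8L2, a chemokine gene of the interleukin-8 type, was at least 2.35-fold higher (adjusted p = 0.216) and LY6CLEL at least 7.79-fold (adjusted p = 0.713). HAND1 was at least 2.31-fold lower here. Erythrocyte genes were higher for 15 of 16 (median 0.21, list adjusted p = 0.0431, adjusted p = 0.895 with an estimated correlation), apoptosis genes had a median of 0.15 (list adjusted p = 0.0431, adjusted p = 0.895 with an estimated correlation) and cardiac transcription factors of -0.25 (list adjusted p = 0.0431, adjusted p = 0.895 with an estimated correlation). The apoptosis call ended with median centring (adjusted p = 0.0576, against 0.0405 with quantile normalization), and the mean of all probe sets ended it and that of the transcription factors (0.0691 for both). Of the outside markers, the liver mean was 6.07 against 5.13 in the normal right, and the liver list (median 0.58, or 0.00 with pool values under 5 set to 5, list adjusted p = 0.312) was not called. Nor was the W list (median 0.34, list adjusted p = 0.198), while Z-linked genes lay at percentile 4.83 of random lists (median -0.06). With the additive model AVD (adjusted p = 0.00293) and IL8L2 (0.00693) passed, and with no other alternative that kept the pool as the unit.

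Which changes do the 2 ligated ventricles share? In their mean no probe set passed in limma, with 1350 at unadjusted p under 0.05. SNAP25, a synaptic vesicle fusion protein, was 1.33 ± 0.16 higher (adjusted p = 0.600) on its brightest probe set and 0.07 to 1.88 over all 4. MYBPC1 was 1.31 ± 0.16 higher (adjusted p = 0.600) and CCN3, a matricellular protein, at least 6.25-fold higher (adjusted p = 0.671). HAND1 was at least 3.53-fold lower (adjusted p = 0.671) and ELN 1.66 ± 0.32 on the log2 scale. FADD, the adaptor of death receptors, was 1.33 ± 0.22, and TMEM100, an endothelial membrane protein, 0.77 ± 0.13 (adjusted p = 0.671). At least 2-fold differences in this mean, with no overlap between the ligated and the normal arrays, came to 240 probe sets higher and 279 lower. On the ligated arrays the middle probe set of the actin control lay 0.13 to 0.30 below its 3' probe set, on those of left and right E6 0.19 to 0.24 below, and on no other array more than 0.12 below. The other control ratios did not set these arrays apart. The 5' actin probe set lay 0.33 to 0.44 below on them and 0.44 below on a normal left E8 array. For GAPDH 5' minus 3' was 0.35 to 0.38 on ligated arrays, 0.26 to 0.32 on left and right E6 and 0.33 to 0.36 on right E10.

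By group, leukocytes and thrombocytes (median 0.44, list adjusted p = 0.00619, adjusted p = 0.739 with an estimated correlation), apoptosis (median 0.21, list adjusted p = 0.0238, adjusted p = 0.739 with an estimated correlation) and endocardium (median 0.13, list adjusted p = 0.0307, adjusted p = 0.739 with an estimated correlation) were higher, with 3 endocardial genes past the test over the list alone. Cardiac transcription factors (median -0.25, list adjusted p = 0.0238, adjusted p = 0.739 with an estimated correlation) and the contractile apparatus (median -0.08, list adjusted p = 0.0238, adjusted p = 0.739 with an estimated correlation) were lower. The skeletal muscle list (median 0.35, list adjusted p = 0.0442, adjusted p = 0.739 with an estimated correlation), to which MYBPC1 belongs, was higher. So were the liver list (median 1.50 as deposited, also where levels are under 5, list adjusted p = 0.0238, adjusted p = 0.739 with an estimated correlation) and the W chromosome list (median 0.42, list adjusted p = 0.0238, adjusted p = 0.739 with an estimated correlation). Z-linked genes had a median of -0.04 here, at percentile 11.4 of random lists. Quantile normalization ended the calls of the contractile list (adjusted p = 0.0625, against 0.0267 with median centring) and of skeletal muscle (0.0509, and 0.0501 with median centring). The mean of all probe sets ended those of the contractile list (0.0753) and of the endocardium (0.0855). A single side can drive the mean of the ventricles. Of the lists named here, only apoptosis and cardiac transcription factors were also called in the right ventricle by itself.

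**Figure D4:**
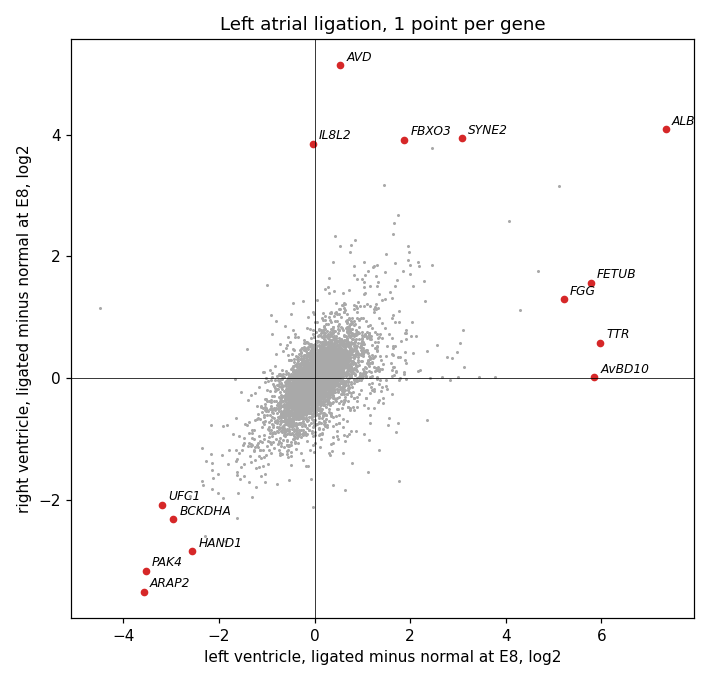
Ligated minus normal difference on the log2 scale at E8 in the left (horizontal axis) and the right ventricle (vertical axis), 1 grey point per gene from 1 pool per condition, with named genes in red. ALB lies far to the right at 7.34 and 4.09, HAND1 at -2.56 and -2.85, drawn as deposited also where a level is under 5, and no gene shown passed the limma test.

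Does ligation act differently on the 2 sides? No probe set passed in limma, with 172 at unadjusted p under 0.05 and a smallest adjusted p of 0.836. Of the 4 pools compared, AVD (adjusted p = 0.836) and IL8L2 (adjusted p = 0.886) were over 5 in the ligated right alone, so their differences have no exact size. By group, oxidative phosphorylation was lower for 35 of 38 genes in the left contrast (median -0.12, list adjusted p = 1.32e-05, adjusted p = 0.876 with an estimated correlation) and cushion and valve genes higher for 11 of 15 (median 0.42, list adjusted p = 0.000935, adjusted p = 0.876 with an estimated correlation). Leukocyte and thrombocyte genes (median 0.39, list adjusted p = 0.00508) and liver genes (median 2.99 as deposited, list adjusted p = 0.0387) were higher in the same contrast. With an estimated correlation both had an adjusted p = 0.876. PRRX1 (2.55 ± 0.64) and MSX2 (at least 4.69-fold) leaned to the ligated left. PRRX1 was lower in the normal left ventricle at E8 (log2 5.54) than in the normal right (8.55), and after ligation the levels were 8.52 and 8.98. In normal hearts its left minus right value was -0.48 at E6, -3.01 at E8 and -1.68 at E10, so the normal E8 pair weighs on this contrast. With the additive model AVD (adjusted p = 0.0174) and IL8L2 (0.0222) passed, and with no other alternative that kept the pool as the unit.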

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

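The tests of the liver, W chromosome and ligation patterns, of a chamber by day term and of the splits within stages given here were chosen only after the results were seen, whereas the list tests and the 10 splits of the single-ventricle pools were planned.

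Between the left and the right ventricle, the test of the difference itself set 7 gene lists apart in the ligated minus normal difference, each with an adjusted p = 0.876 with an estimated correlation. As left minus right medians of the ligation difference, cushion and valve genes were at 0.42 (adjusted p = 0.000935), leukocytes and thrombocytes at 0.39 (0.00508) and matrix and fibroblast genes at 0.29 (0.0104). The Wnt pathway was at 0.26 (0.0160) and liver genes at 2.99 (0.0387), or 0.74 with pool values under 5 set to 5. Oxidative phosphorylation was at -0.12 (1.32e-05) and erythrocytes at -0.20 (0.0103). The cushion, leukocyte, matrix and erythrocyte lists were called in the opposite direction between the normal left and right ventricles. The normal E8 pools, 1 per side, enter this difference too, so a response to ligation cannot be told from a normal E8 pair that stands apart.

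In normal hearts the left minus right difference of 11 named genes had the opposite sign at E6 to that at E8 or E10, with no overlap between the arrays compared. A chamber by day term, with 2 residual degrees of freedom, passed for 0 probe sets in limma (smallest adjusted p = 0.379, and 0.401 among the 11), so a change between stages is not shown. The term is linear in day, so it could not show a sign that turned at E8 alone, as for HAND2 (0.29 at E8), TTR, FGB and FGG. At E6 the log2 difference was 0.35 for MYH7, 0.44 for MYH11, 0.0905 for BGN, 0.26 for NPPA and 0.14 for MYL2. It was -0.38 for SEMA3D and -0.14 for HAND2. At E10 it was -0.83 for MYH7 and 0.99 for SEMA3D, and MYH11 and BGN were lower in the left, at levels under 5 there. Among liver genes it was 4.32 for TTR, 0.70 for FGB, 0.55 for FGG and -0.20 for ALB at E6. Both E6 levels of BGN, FGB, FGG and ALB and the right E6 and left E8 levels of TTR are under 5, so these signs are not well measured. Left and right pools were also regrouped into all 10 splits of 3 and 3: 2 of the 10 splits, the real one included, gave as many probe sets at unadjusted p under 0.05. The real split gave 2155 and the highest other, with left E6, right E6 and right E10 on one side, 2282. With 3 pools against 3 the share cannot go under 0.1. Among the 4 splits that keep the pools of a stage on opposite sides the real one gave the most, against 108 to 1601, a share that cannot go under 0.25.

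Signal also appeared in 4 probe sets whose names lie outside the chicken gene design. Their highest pool means were 12.80, 8.16 and 7.35 in right E10 and 8.15 in right E8, and the lowest pool means of these 4 were 8.85, 3.76 and 3.39 in the ligated left ventricle and 5.63 in the E6 pool of both ventricles.

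In the mean of the 2 ligated ventricles 279 probe sets were at least 2-fold lower than in the normal ones, with no overlap between the arrays compared. In unoperated E6 hearts these same probe sets had a median of -0.83 in the left and right pools against the pool of both ventricles (-0.02 over all tested), which RNA preparation or labelling shared by those pools predicts. Ligation as the whole cause predicts no such shift, and 65.9% of them lay over 0.5 lower there, against 7.55% of all tested probe sets. After removal of the part parallel to the E6 difference 219 of the 279 were still at least 2-fold lower, with their median moving from -1.32 to -1.20. The slopes of that part over all probe sets were only 0.144 in the left (r = 0.136) and 0.263 in the right (r = 0.263). Such slopes could move these probe sets little whatever the cause, so the removal cannot decide. Ligation may be a part of the cause, which stays open. Of the 240 probe sets at least 2-fold higher, 36.7% lay over 0.5 higher in the E6 left and right pools, against 5.55% of all tested probe sets. Their median there was 0.22. After the removal 204 stayed 2-fold (median 1.37, then 1.33). Of 127 other probe sets of the genes of the 279, 33.9% were also at least 0.5 lower (median -0.34). Of 140 other probe sets of the genes of the 240, 20% were at least 0.5 higher (median 0.09). The share among all tested probe sets was not computed for these other probe sets.

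The 9 tested liver genes were higher in the ligated left ventricle by a median of 1.62 with pool values under 5 set to 5 (3.0 as deposited), with ALB at 6.45, TTR at 4.30 and FGG at 2.90. Ligation as the only source is argued against by the unoperated E6 pool of both ventricles, which held them at a median of 3.60 above the mean of left and right E6 at the same bound (4.94 as deposited). Liver tissue carried over in dissection predicts that the genes rank alike in the 2 pools, and Spearman's rho over the 9 genes, which are not independent, was 0.8, or 0.795 at the bound. APOA1 and TF were at high levels in every pool (from 10.4 and 11.4) and had the smallest differences on both sides as deposited. This raises rho whatever the source, so rho alone cannot decide. The gene with the largest difference as deposited was ALB in the ligated left (7.34) and FGG in the E6 pool (6.05). Of the 18 listed genes on the array, 9 were not tested. Liver tissue may thus have entered both pools, and a ligation response on top of it stays open and untested.

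W chromosome genes were higher in the banded pool by a median of 0.91. Banding that acts on W genes alone predicts no shift of Z-linked genes, yet the median of 24 Z-linked genes, -0.09, lay at percentile 0.27 of 10000 random lists matched on expression. More female embryos in the banded pool predict that value, and 15 of the 24 were lower. The W mean also varied among normal pools, from 9.29 in right E10 to 10.1 in right E8, against 9.44 in left E8. The sex ratio of the pools may thus differ, but for left and right of a stage only if they come from different embryos. The sex of the embryos, and whether left and right came from the same ones, is not given in the labels, and an effect of banding besides it stays open and untested.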

How the results depend on the processing

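Results without the left and right E6 pools (for E6 minus E4, with E6 from the pool of both ventricles alone) or with the E6 component removed are alternatives chosen after seeing the data. All other alternatives were planned. Signal over background limits genes under 5 on the log2 scale, above the highest unspiked control of 3.35, and n = 1 pool per condition limits every count. The cause of a change was not tested, except that fewer pools or a stricter scatter leave less to test with. Of 13824 values of named genes under the alternatives, 12092 kept their direction and their side of the threshold, 1172 passed newly (1084 of them with arrays counted as samples), 458 no longer passed and 102 turned sign. In comparisons without a call none could be lost, and leaving out E4 or E5 cannot change E10 minus E6. The total therefore says little on how stable the calls are.

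Counting arrays as samples sets hybridisation noise in place of the scatter between pools. The count then rose to 14131 for the age slope, 10662 for E6 minus E4, 13046 for E10 minus E6, 9584 for left minus right, 1907 for CTB, 8752 and 8068 for the ligated left and right, 10578 for their mean and 3590 for their difference. With the replicate number as a replicate block these were 14115, 10643, 13025, 9508, 1846, 8678, 8051, 10556 and 3557. Arrays share only a number, since over 66 pairs of pools the deviations of same-numbered arrays had a median r of 0.00463 and a highest r of 0.0834, with 0 above 0.1.

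With 1 pool left out in turn or a single array per pool, the count for the age slope ran from 1577 to 4124, for E6 minus E4 from 12 to 73 and for E10 minus E6 from 30 to 1118. E4 could not be left out of E6 minus E4. The slope count was 1349 in the 6 single-ventricle pools. E6 minus E4 gave 111 with median centring, of which 70.3% were higher against 59.1%, 207 with no filter, of which 30.9% were, and 100 with a trended and robust variance. E10 minus E6 gave 529 with no filter and 252 without the left and right E6 pools. Median centring moved the higher share of the slope from 42.6% to 52.4%. The trended and robust variance gave 5 for left minus right. A filter at 7 gave 1 for CTB. The additive model gave 1 for CTB, 1 and 5 for the ligated left and right, 6 for their mean and 2 for their difference. For CTB the probe set was that of AVD, and for the difference those of AVD and IL8L2. With the E6 component removed the count was 0 in all 4 ligation results. Of the list tests, 0 held in any of the 9 comparisons with an estimated correlation. With the mean of all probe sets 1 list held for the ligated right.

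With median centring the values with a turned sign were, for the age slope, IRX4 at 0.0116. For E6 minus E4 they were HAND2 at 0.0202 and IRX4 at 0.0248. For the ligated right they were MYH15 at 0.0174, MYL2 at 0.0189 and TNNT2 at 0.0149. In the 6 single-ventricle pools alone the values with a turned sign were, for the age slope, NR2F2 at -0.19, HAND1 at 0.0145 and IRX4 at 0.0103. With quantile normalization the values with a turned sign were, for E6 minus E4, HAND2 at 0.0116 and MYL2 at -0.0506. For E10 minus E6 they were IRX4 at -0.0341. For CTB they were NPPA at 0.0399 and MYL2 at 0.0204. For the ligated right they were MYL2 at 0.0137 and TNNT2 at 0.00247. For the ligated mean they were NPPA at 0.00218 and MYL2 at 0.00685. For the ligated left minus right they were GJA5 at 0.00432 and IRX4 at 0.00971. With E6 taken from the both-ventricle pool alone the values with a turned sign were, for E6 minus E4, MYBPC2 at 0.13, TNNC2 at -0.0261, NPPA at -0.0392, HAND2 at 0.12, IRX4 at 0.0667, MYH15 at -0.0210, MYL2 at -0.0155 and GJA1 at -0.39. Without the E6 left and right pools the values with a turned sign were, for E10 minus E6, MYBPC2 at -0.16 and IRX4 at -0.0697. For left minus right they were CDH1 at -0.00615 and MYL2 at -0.0154. With the additive model the values with a turned sign were, for the ligated left, KCNJ3 at 0.12. For the ligated right they were MSX2 at 0.0251 and CDH1 at 0.0872. For the ligated left minus right they were TBX5 at 0.52, BNC1 at -0.0607, MYBPC1 at 0.0651 and IRX4 at 0.0880. With the E6 component removed the values with a turned sign were, for the ligated right, CDH1 at 0.14. For the ligated mean they were MYH7 at 0.0383.

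With pools or arrays left out, these named genes ran to both sides of 0. For the age slope the range was APOB -0.31 to 0.00415, STMN2 -0.13 to 0.31, TNNT3 -0.0106 to 0.0241, IRX4 -0.00380 to 0.00708 and GJA1 -0.0658 to 0.0119. For E6 minus E4 the range was MYBPC2 -0.52 to 0.13, NPPA -0.0485 to 0.0505, TBX5 -0.0914 to 0.95, HAND2 -0.0779 to 0.0809, IRX4 -0.0441 to 0.0299, MYH15 -0.0236 to 0.0417, MYL2 -0.0361 to 0.0343, TNNT2 -0.0270 to 0.19 and GJA1 -0.20 to 0.21. For E10 minus E6 the range was MYBPC2 -0.16 to 0.69, HAND1 -0.91 to 0.0581, IRX4 -0.0370 to 0.0454, MYL2 -0.0224 to 0.20 and TNNT2 -0.0272 to 0.0862. For left minus right the range was CDH1 -0.0749 to 0.34, TTR -0.40 to 3.48, FGB -0.75 to 1.45, FGG -1.27 to 1.42, ALB -0.93 to 1.42, CSPG4 -0.12 to 0.54, HAND2 -0.14 to 0.0954 and MYL2 -0.00508 to 0.11. For CTB the range was NR2F2 -1.01 to 0.19, TBX5 -0.00952 to 0.33, TNNT3 -0.33 to 0.0106 and NPPA -0.0480 to 0.0410. For the ligated left the range was KCNJ3 -0.92 to 0.22 and CKMT2 -1.23 to 0.0750. For the ligated right the range was CDH1 -0.43 to 0.36, MYL2 -0.0537 to 0.0342 and TNNT2 -0.0491 to 0.0216. For the ligated mean the range was MYH7 -0.0324 to 0.00425. For the ligated left minus right the range was HEMGN -0.97 to 0.0512 and IRX4 -0.0133 to 0.00487.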

Other observations

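The test of delayed development given in this part was chosen only after the result was seen.

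Single transcripts known from epithelia were higher in the E4 pool than at E6, picked from the calls of E6 minus E4. With a single E4 pool, a fall with age cannot be told from a trait of that pool, such as tissue taken along with it. Besides AGR2 and TFF3 there was PLET1, which fell at least 4.42-fold to E6 (adjusted p = 0.00202 in limma), and MAL, a membrane protein of epithelia and myelin, which fell at least 2.14-fold (adjusted p = 0.00338). Of the foregut and lung epithelium list only EPCAM and CDH1 were tested, too few for a list test, and EPCAM, an epithelial adhesion protein, fell with age by 0.32 ± 0.05 per day (adjusted p = 0.00361). LOC420770 was at log2 13.96 at E4 and 5.47 at E5. BNC1, a zinc finger gene of the mesothelium and the epicardium that was under 5 in some pools, had a slope of -0.43 ± 0.05 per day (adjusted p = 0.00201).

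The neural and neural crest list was not called for the age slope (list adjusted p = 0.50). Single genes fell. GAD1, for the enzyme that makes the transmitter GABA, was under 5 in some pools and fell by 0.87 ± 0.12 per day (adjusted p = 0.00330), and CHODL, a membrane lectin of motor neurons and muscle, by 0.96 ± 0.17 (adjusted p = 0.00750). In the operated hearts AVD stood apart: its log2 level was 8.01 after banding, 7.42 in the ligated right ventricle and 2.84 in the ligated left, and 2.27 in normal E5. IL8L2 was at 6.24 in the ligated right ventricle and 2.39 in the ligated left.

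The ligated ventricles leaned against the normal change from E6 to E10. Of the 1118 probe sets called in that interval, 75.9% differed in the opposite direction in the mean of the ligated ventricles, 75.8% in the left and 68.9% in the right. With the part parallel to the E6 left and right difference removed, which could change little, the share was 73.8%, above the bound set for delayed development after ligation. Among all tested probe sets it was 65.6%, which also lies above that bound, so the test separates little. In the banded pool at E5 it was 52.4%, and with the left and right E6 pools left out of the normal fit it was 74.6% of 252. A delay may contribute, but 1 pool per condition leaves it a hypothesis.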
